A study of Mus musculus with 16 samples.

How the data were processed

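The data are RNA sequencing libraries of mouse ES-E14TG2a cells with an shNT or an shBeclin1 hairpin, 16 in 8 groups of 2, at day 0, day 4 and day 10, the last in cells labelled CM and in cells labelled CM without GF. Per the labels, total RNA was taken with TRIzol and libraries were made with an rRNA depletion kit and a stranded mRNA kit, then read in pairs on a HiSeq X 10; the molecule tag says polyA RNA, so which RNA fraction was kept is not settled. A tissue tag says heart although the samples are a cell line and its derivatives. The authors deposited 1 table of raw counts per gene symbol with 54052 entries and 1 count column per library, and all columns were assigned to a library. Per the submitters' processing notes, reads were handled with Trimmomatic 0.36, featureCounts, Subread 1.5.1 and SAMtools against mm10; the role and order of these tools, the aligner, the annotation and the strand setting are not given in the sources used here. The column names end in count and all values are whole numbers with column sums from 14967744 to 21422980. Of the entries, 18471 were 0 in all libraries and 882 repeated a symbol (77 symbols) and were kept apart. Of the symbols, 93.8% were found in the gene name table. Totals per library are given with the results.

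Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups, which removed 34911 entries and left 19141. Libraries were scaled with TMM (normalization factors 0.884 to 1.078), and a robust quasi-likelihood negative binomial model with 1 mean per group and no intercept was fitted to all 16 libraries. That left 8 residual degrees of freedom, with a common biological coefficient of variation of 5.4% and a median of 27.8 prior degrees of freedom. No batch term could be fitted as the batch tag repeats the group, and no replicate block was used as the labels pair no replicates. The correlation of replicate differences between hairpins, 0.07 at day 0, -0.03 at day 4, -0.02 at day 10 and -0.03 without GF across genes, gave no sign of pairing. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and the standard error of a log2 fold is its size over the root of the F statistic. The comparisons were shBeclin1 against shNT at each of the 4 points, day 4 and day 10 against day 0 in shNT, CM against CM without GF within each hairpin, shBeclin1 without GF against shNT CM, and differences of knockdown effects between day 4 and day 0, day 10 and day 0, and the day 10 cultures. Other splits of the libraries and tests for outlying libraries, which ask for larger groups than 2, were not run.

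Genes named in the text follow a rule: Becn1, then per knockdown comparison the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 2, replicates that do not overlap and no predicted-gene symbol. From the lists pluripotency, streak, cardiac progenitor, cardiomyocyte, Wnt target, BMP target and core autophagy, and from any list called, the 3 called members with the smallest adjusted p are added, filled up to 2 by expression. Other comparisons take 4 rises and 4 falls. The rule names 237 genes, of which the text gives a part. Members named because 5 or fewer of a list moved one way, and others where stated, were chosen after their values were seen. A fold against a group at 0 counts is computed against a floor of 3 counts over the group and written as at least that fold, and with 1 to 3 counts the ratio is given with its 95% counting interval.

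The 37 gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, adjusted over lists within a comparison. They cover pluripotency, formative and primed cells, primitive streak and mesendoderm, cardiac progenitors, cardiomyocytes, epicardium, smooth muscle and fibroblasts, blood and endothelium, skeletal muscle, definitive endoderm, visceral endoderm and liver, neuroectoderm, trophoblast, keratin and epithelium, and Hox genes. They also cover Wnt ligands and receptors, targets and antagonists, BMP ligands and receptors, targets and antagonists, Nodal and Activin, FGF and ERK targets, Notch, core autophagy, lysosome, cell cycle, interferon, p53, unfolded protein and integrated stress responses, Nrf2, immediate early genes, hypoxia and glycolysis, oxidative metabolism, ribosomal proteins, mitochondrially encoded genes and replication histones. Some genes sit in several lists, such as T in the streak and Wnt target lists and Kdr in the cardiac progenitor and blood and endothelial lists. Lists were tested in the knockdown comparisons and their differences. Beside camera, the estimated inter-gene correlation and fry, which tests whether a list's own members move one way, were run. Genes of normal differentiation were the 200 most raised and 200 most lowered of an shNT contrast outside the tested libraries. Overlaps of called genes were set against independence with Fisher's exact test, where genes are not independent. Coordinates and exon overlaps come from GENCODE vM21 on GRCm38, the assembly that mm10 names, counted from 1; this annotation need not be the one used for counting.

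Samples, comparisons, lists, naming rule and alternatives were fixed before the data were examined, except those that the text names as chosen later. The alternatives were RLE size factors or total counts for TMM, no low-count filter or a strict one (CPM of at least 1 in at least 4 libraries), DESeq2 1.42.0 or limma-voom for edgeR, a replicate block within day or across days, leaving out each library, a fold of at least 2, a fit of only the groups compared, and 100 or 400 genes of differentiation. A pseudocount was not varied, since that applies to normalized values. The method was tested on simulated data made from each comparison's counts. At day 0, on 18847 genes, edgeR recovered 71.6% of genes changed 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 2.5% false calls. At day 4, on 18851 genes, it recovered 76.1%, 92.5% and 97% with 5.3% false calls; at day 10, on 18828 genes, 73.1%, 95.5% and 100% with 7%; and at day 10 without GF, on 18762 genes, 79.1%, 95.5% and 100% with 6.8%. A list of 25 genes changed 1.5-fold was found by camera in all 4, and of 200 unchanged lists none, 4, 2 and 1 had a p under 0.05. Simulated genes varied independently, so these lists cannot show how camera behaves where members vary together. Besides the changed list, only 66 or 67 expressed genes were changed at each fold. In real knockdown comparisons 13.3 to 54.7% of genes were called and replicate spread differed by group, so these rates need not hold. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.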

Results

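RNA was sequenced from ES-E14TG2a cells, a mouse embryonic stem cell line, that carried a short hairpin against Beclin1 (shBeclin1) or a hairpin labelled shNT, taken here as the control. Beclin1, the product of Becn1, is a subunit of the lipid kinase complex that starts autophagosome formation. The 16 libraries make 8 groups of 2, with both hairpins at day 0 (embryonic stem cells), at day 4 (embryoid bodies), at day 10 (cells labelled CM) and at day 10 in cells labelled CM without GF; below, day 10 alone means the CM culture. The labels neither spell out GF nor say that cells labelled CM had it or that replicates were separate cultures. P-values thus need not cover variation between cultures. The labels give only the name shBeclin1 for the hairpin, and no sample is labelled as a rescue. Effects of knockdown are therefore differences between shBeclin1 and shNT cells. Loss of Becn1 cannot be told apart from other effects of the hairpin or of the cells that carry it. The study asked what lies behind more cardiomyocyte differentiation after Beclin1 knockdown, with Wnt and BMP signalling named in its title. Total counts per library in the order replicate 1 and 2 were 15291658 and 15463801 for shNT and 15528592 and 15819830 for shBeclin1 at day 0. At day 4 they were 15584415 and 16021923 for shNT and 16798092 and 20340048 for shBeclin1. At day 10 they were 21422980 and 15801238 for shNT and 15574140 and 17214564 for shBeclin1. Without GF they were 14967744 and 16408357 for shNT and 16744240 and 18652200 for shBeclin1. Levels below are TMM-scaled CPM as mean ± SD with n = 2 libraries per group, and folds and adjusted p-values come from the edgeR fit over 19141 genes. The intervals of Becn1 come from the standard error of that fit, while ratios from few counts, with their counting intervals, and floors for groups at 0 counts cover counting error only.

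Libraries separated by day, and by hairpin most widely at day 10. The first principal component of log2 CPM, with 52.7% of the variance, placed day 0 libraries between -149.1 and -143.7 and day 10 libraries between 71.5 and 128.1. The second component, with 22.6%, set day 4 libraries apart (110.1 to 119). The third component, with 11.4%, placed day 10 shBeclin1 libraries between 43.4 and 65.6 and day 10 shNT libraries between -110 and -36.9; both ranges include the libraries without GF. On that component the hairpins lay closer at day 4 (20 to 22.1 for shBeclin1, 10.8 to 11.1 for shNT) and at day 0 (2.6 to 3.8 for shBeclin1, 0.7 to 2.5 for shNT). Log2 CPM of replicates correlated at 0.9923 to 0.9959 across genes, which are not independent replicates. The 2 day 0 shNT libraries differed most, with a median absolute log2 difference of 0.154 against 0.077 to 0.118 in the other groups. Ribosomal RNA took 0.229 to 0.501% of counts and the 20 most abundant genes took 6.65 to 9.76%. The batch tag in the labels repeats the group name, so batch and group cannot be told apart in any comparison below.

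**Figure D1:**
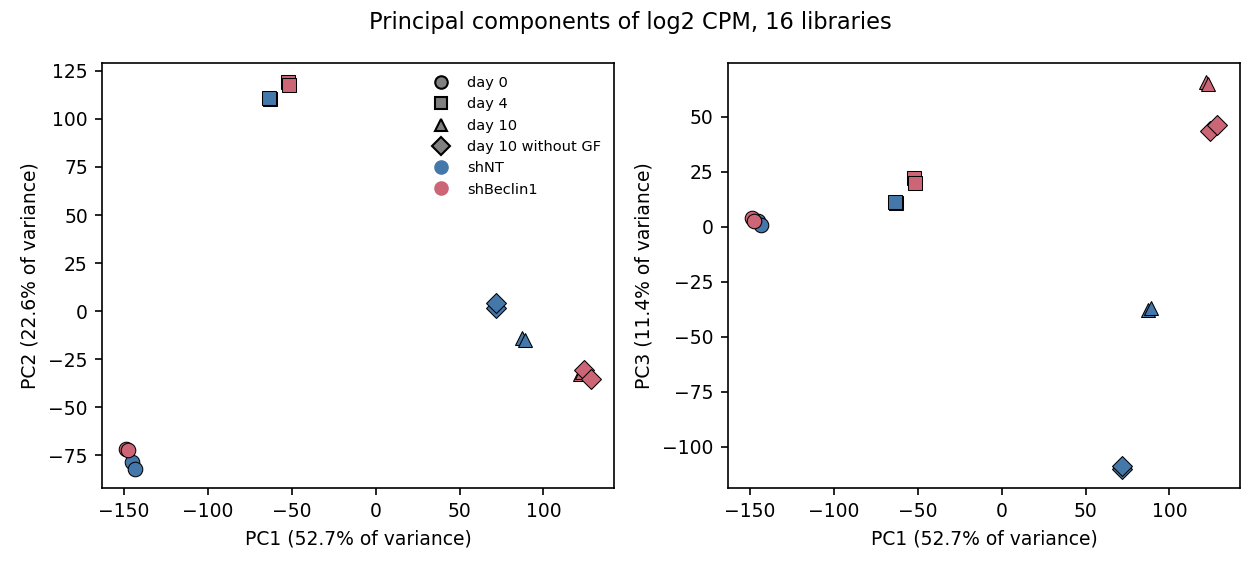
Principal components of log2 CPM, with each point 1 of 16 libraries, colour the hairpin and shape the day; the axes are component 1 (52.7% of variance) against component 2 (22.6%) and component 3 (11.4%), in arbitrary units. Replicates lie close together, and on component 3 the lowest day 10 shBeclin1 library lies at 43.4 and the highest day 10 shNT library at -36.9.

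Becn1 was lower in shBeclin1 than in shNT libraries at all 4 points, and the difference was smaller at day 10. At day 0 Becn1 stood at 38.1 ± 2.66 CPM in shBeclin1 against 87.2 ± 2.9 CPM in shNT libraries, so 43.7% remained (95% interval 39.4 to 48.4). At day 4 it stood at 36.1 ± 3.29 against 72.6 ± 0.542 CPM, or 49.8% (44.9 to 55.3). At day 10 it stood at 36.6 ± 0.385 against 59 ± 1.06 CPM, or 62.1% (55.9 to 68.9), and without GF at 44 ± 1.78 against 62.2 ± 1.83 CPM, or 70.8% (63.9 to 78.4). The adjusted p-values in the order of these comparisons were 2.42e-13, 6.23e-13, 1.77e-09 and 5.17e-07. The log2 difference was smaller by 0.51 at day 10 than at day 0 (SE 0.11, adjusted p = 0.000389); at day 4 it was not shown to differ from day 0 (0.19, adjusted p = 0.272). Becn1 lies on chromosome 11 at 101285952 to 101302286 of GRCm38 (mm10), on the minus strand with 10 merged exons in GENCODE vM21. Exons of Cntd1 on the opposite strand cover 43.9% of its exon length, and the strand setting of the counting is not given in the sources used here. Cntd1 itself stayed between 0.75 and 4.9 CPM. Exons of other genes also cover part of the exon length of Smarcd3 (48.2%), Hopx (27.2%), Rpl5 (24.3%), Tbx18 (20.6%), Dll1 (20.5%), Hand2 (19.6%), Sqstm1 (17.3%), Lef1 (13.7%) and Ctsb (12.8%), so counts of these genes can include reads of a neighbour.

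**Figure D2:**
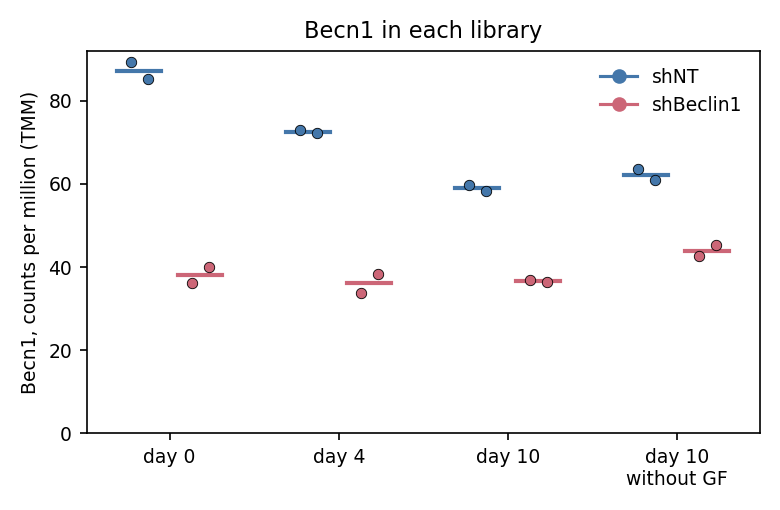
Becn1 in TMM-scaled CPM on the vertical axis, by day and by hairpin, with points for libraries and lines for the mean of 2. In each comparison both shBeclin1 libraries lie below both shNT libraries, at means of 38.1 against 87.2 CPM at day 0 and 44 against 62.2 CPM at day 10 without GF.

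The shNT libraries alone show how the cultures changed with time in the absence of knockdown. From day 0 to day 4, Fgf5, a growth factor of primed cells of the epiblast, rose from 0 to 218 ± 2.14 CPM, at least 2300-fold over the floor of 3 counts per group, and Lhx1 rose at least 1730-fold. Sema6a rose 1030-fold to 138 ± 2.51 CPM, while Nupr1 fell 165-fold from 80.4 ± 9.76 to 0.478 ± 0.085 CPM. From day 0 to day 10, the collagen gene Col3a1 rose from 0 to 949 ± 113 CPM (at least 10100-fold), the endothelial cadherin gene Cdh5 rose at least 2510-fold and Ptn at least 2680-fold. The pluripotency regulator Prdm14 fell 63.5-fold from 53.4 ± 1.35 to 0.82 ± 0.14 CPM. By day 4, 6567 genes rose and 6245 fell, 6610 of them by at least 2-fold; with total counts as the scaling, the median log2 fold of all genes at day 4 shifts by -0.118. By day 10, 7044 rose and 6765 fell, 7835 of them by at least 2-fold.

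At day 0 the question is what knockdown does to undifferentiated stem cells. Dppa3, a gene of naive pluripotent and germ cells, rose 3.51-fold, from 10.2 ± 1.75 CPM in shNT to 36 ± 0.352 CPM in shBeclin1 libraries (adjusted p = 5.45e-12). The FGF receptor gene Fgfr2 rose 3.27-fold to 8.5 ± 0.683 CPM, and the X-linked homeobox gene Rhox5 rose 2.53-fold to 86.3 ± 3.07 CPM. Etv4, a transcription factor induced by FGF signalling, fell 2.92-fold from 18.1 ± 2.65 to 6.17 ± 0.111 CPM, and the Wnt antagonist gene Dkk3 fell 2.84-fold from 17.6 ± 0.267 to 6.21 ± 0.796 CPM. The calcium channel gene Cacna1h fell 3.34-fold to 2.2 ± 0.16 CPM. In all, 1109 genes rose and 1446 fell, and 80 and 214 of these changed at least 2-fold; the unadjusted p was under 0.05 for 5051. Of the called genes 43.4% rose, and 23.9% with total counts in place of TMM as the scaling. Without day 0 shBeclin1 replicate 1 the count was 1160, without shBeclin1 replicate 2 it was 920, and in a fit of the 4 day 0 libraries alone it was 1241. Counts of the 2 shNT libraries differed with a chi-square per degree of freedom of 8.77, against 1.72 between the shBeclin1 libraries and 9.79 to 13.89 between hairpins, and ribosomal protein genes took 8.24 and 7.08% of their counts.

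The core pluripotency list did not move as a whole at day 0. Of its 20 genes 4 rose, among them Dppa3 and Tdh, and 3 fell, among them Tdgf1 from 1510 ± 66.6 to 1140 ± 5.53 CPM, with the same counts adjusted over the list alone (adjusted p = 0.571 for the list). Of 16 primitive streak and mesendoderm genes none was called by edgeR; Eomes stood at 6.75 against 6.11 CPM (adjusted p = 0.562) and T at 0.194 against 0.317 CPM (adjusted p = 0.575). Of 20 cardiac progenitor genes 3 fell and none rose (4 and none adjusted over the list alone), namely Fgf10 (12.8 ± 2.08 to 6.79 ± 0.437 CPM), Smarcd3 (9.03 ± 0.518 to 5.53 ± 0.286 CPM) and Hopx (0.761 to 0.0646 CPM); the list was not called (adjusted p = 0.0521), the Hopx call ended without shBeclin1 replicate 2 (adjusted p = 0.0539), and without shNT replicate 2 the list was called (adjusted p = 0.036). Cacna1c was the 1 cardiomyocyte gene of 32 that fell (2.72 ± 0.413 to 0.934 ± 0.493 CPM), a call that ended without shNT replicate 2 (adjusted p = 0.0642) or without shBeclin1 replicate 1 (adjusted p = 0.0847). Among 22 Wnt target genes 3 rose, Myc (1.58 ± 0.338 to 3.52 ± 0.191 CPM) with Tnfrsf19 and Ccnd1, and Cdx1 and Tcf7 fell. The Cdx1 call ended without shNT replicate 2 (adjusted p = 0.146), shBeclin1 replicate 1 (0.123) or shBeclin1 replicate 2 (0.115), and the Tcf7 call without shNT replicate 1 (0.173) or shBeclin1 replicate 2 (0.294). Among 20 BMP target genes, Id4 rose to 11.1 ± 0.208 CPM, Id2 rose to 9.2 ± 1.59 CPM and Smad9 fell to 0.774 ± 0.175 CPM. The Id4 call ended without shBeclin1 replicate 2 (adjusted p = 0.0604) and without shBeclin1 replicate 1 (adjusted p = 0.0748), and the Id2 call without either shNT replicate (adjusted p = 0.078 and 0.274) or without shBeclin1 replicate 2 (0.313). The Smad9 call ended without shNT replicate 1 (adjusted p = 0.131) and without shBeclin1 replicate 1 (0.102).

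Camera called 5 lists at day 0 with a preset correlation and none with an estimated one. Of 11 formative and primed pluripotency genes 6 rose and none fell (6 and 1 adjusted over the list alone), such as Dnmt3b (35.2 ± 0.804 to 48.7 ± 0.631 CPM) and Zic2 (32.5 ± 0.928 to 46.3 ± 0.976 CPM). Camera gave adjusted p = 0.0217, and adjusted p = 0.405 with an estimated correlation. That call ended without shNT replicate 2 (0.13) or without shBeclin1 replicate 1 (0.085). Of 25 hypoxia and glycolysis genes 13 fell and Gapdh rose (18 and 1 adjusted over the list alone), with P4ha2 falling from 38.3 ± 1.56 to 24.7 ± 1.22 CPM. The list had adjusted p = 9.59e-07, and adjusted p = 0.74 with an estimated correlation. Of 22 genes of the unfolded protein and integrated stress responses 6 fell and none rose, with the same counts adjusted over the list alone, among them Ddit3 (59 ± 5.23 to 37.8 ± 1.11 CPM) and Ddit4 (56.1 ± 5.28 to 36.8 ± 2.03 CPM). As a list they had adjusted p = 0.0167, and adjusted p = 0.74 with an estimated correlation, and were not called without shNT replicate 1 (0.151) or shBeclin1 replicate 1 (0.0546). Of 36 Hox genes 3 fell (none adjusted over the list alone), namely Hoxa3, Hoxa10 and Hoxc13. Hoxa3 and Hoxa10 rested on few counts, with ratios of 12.7 (counting interval 1.91 to 542) and 11.8 (1.74 to 503). Together the Hox list members had adjusted p = 0.0217, and adjusted p = 0.405 with an estimated correlation. The Hox list call ended with total counts (0.156), with the strict low-count filter (0.175), and without shNT replicate 1 (0.0575), shNT replicate 2 (0.0848) or shBeclin1 replicate 1 (0.0837), and the call of Hoxc13, 6.5 ± 0.571 against 10.1 ± 0.274 CPM, ended in all 4 leave-one-out fits (adjusted p from 0.127 to 0.298). Of 89 ribosomal protein genes 7 rose (none adjusted over the list alone) at a list median of 0.11, or 0.05 with total counts as the scaling. The list test gave adjusted p = 3.92e-07, and adjusted p = 0.74 with an estimated correlation, with a median of -0.01 (adjusted p = 0.953) without shNT replicate 2. Of 42 core autophagy genes 4 rose and 6 fell (6 and 7 adjusted over the list alone), including Wipi1 (33 ± 0.43 to 22 ± 1.5 CPM) besides Becn1; the list was not called (adjusted p = 0.592).

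At day 4 the question is whether knockdown alters the formation of mesoderm in embryoid bodies. T, the gene of the primitive streak factor brachyury, rose 3.38-fold, from 165 ± 1.77 CPM in shNT to 557 ± 0.886 CPM in shBeclin1 libraries (adjusted p = 1.99e-21). Mesp1, which marks the earliest cardiac mesoderm, rose 6.57-fold from 14.2 ± 1.2 to 93.2 ± 7.26 CPM. The VEGF receptor gene Kdr rose 6.33-fold to 149 ± 1.22 CPM, Pdgfra rose 4.56-fold to 204 ± 3.27 CPM and Gata4 rose 4.97-fold to 81.9 ± 4.27 CPM. Wnt2 had the largest rise under the naming rule, 8.65-fold to 18.4 ± 0.274 CPM. Foxd3, a transcription factor of pluripotent cells, fell 3.68-fold to 8.24 ± 0.471 CPM and Irs4 fell 5.86-fold to 6.29 ± 1.34 CPM. In all, 2047 genes rose and 1928 fell, 493 and 470 of them at least 2-fold, and with total counts as the scaling 38.1% rose in place of 51.5%. The count of 3975 became 2514 to 2644 in leave-one-out fits, 2516 without shNT replicate 1, 2514 without shNT replicate 2, 2611 without shBeclin1 replicate 1 and 2644 without shBeclin1 replicate 2. In GRCm38, T lies on chromosome 17 at 8434423 to 8442496, Mesp1 on chromosome 7 at 79792241 to 79793788, Kdr on chromosome 5 at 75932827 to 75978458 and Gata4 on chromosome 14 at 63198922 to 63271692.

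Lists of early mesoderm and of Wnt and BMP targets, some with shared members, rose at day 4. Signalling apart from lineage was not tested. Of 16 primitive streak and mesendoderm genes 11 rose and 1 fell. Evx1 rose from 25.7 ± 0.62 to 115 ± 0.93 CPM and Cer1 fell by 0.60 on the log2 scale. The list had adjusted p = 1.51e-05, and 0.0123 with an estimated correlation. Of 20 cardiac progenitor genes 11 rose and 1, Hopx, fell, at a list median of 1.76 (adjusted p = 8.11e-09, and 0.0123 with an estimated correlation). Of 22 Wnt target genes 16 rose and 1, Lgr5, fell, with Sp5 rising 2.68-fold to 148 ± 15.4 CPM and Lef1 2.07-fold to 154 ± 4.07 CPM. Camera gave adjusted p = 1.88e-07, and 0.0274 with an estimated correlation. Of 20 BMP target genes 13 rose and none fell (15 and none adjusted over the list alone), with Id1 rising 2.98-fold to 53.1 ± 3.84 CPM and Hand1 10.6-fold to 8.36 ± 0.369 CPM. The list had adjusted p = 1.01e-09, and 0.00527 with an estimated correlation. Of 23 blood and endothelial genes 10 rose and 1, Ptprc, fell (from 8 to 0 counts per group), with Etv2 rising 5.31-fold to 29.9 ± 2.36 CPM and Lmo2 7.1-fold to 26.3 ± 1.43 CPM. As a list they had adjusted p = 9.16e-06, and 0.0274 with an estimated correlation. Of 15 Notch pathway genes 8 rose and 2, Dtx1 and Notch3, fell, with Dll1 rising 4.36-fold to 108 ± 3.3 CPM. Together the members had adjusted p = 0.000523, and 0.0448 with an estimated correlation. Counts adjusted over the list alone were the same for the streak, cardiac progenitor, Wnt target, endothelial and Notch lists. Of 32 cardiomyocyte genes only Cacna1c was called, 5.84 ± 0.00141 against 1.78 ± 0.15 CPM, and the list was not (adjusted p = 0.207). Pluripotency genes went both ways, with 6 up and 5 down of 20 (adjusted p = 0.702), as in Tbx3 (5.48 ± 0.523 to 34.6 ± 0.523 CPM) and Utf1 (49.7 ± 5.69 to 18.4 ± 3.67 CPM).

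Other lists moved at day 4 with a preset correlation only. Formative and primed genes fell, 8 of 11 with 2 up (9 and 2 adjusted over the list alone), as in Dnmt3b (2290 ± 9.96 to 1160 ± 4.54 CPM). The list test gave adjusted p = 0.00198, and adjusted p = 0.0571 with an estimated correlation. Lysosome genes fell in 13 of 37 with Npc2 up (15 and 1 adjusted over the list alone). Tested as a group they had adjusted p = 1.51e-05, and adjusted p = 0.129 with an estimated correlation. BMP ligand and receptor genes rose in 6 of 21 with none down (8 and 1 adjusted over the list alone), as in Smad1 (68.5 ± 0.769 to 168 ± 0.621 CPM). Camera gave adjusted p = 0.00157, and adjusted p = 0.238 with an estimated correlation. FGF and ERK target genes rose in 7 of 13 with Spred3 and Spry1 down (8 and 3 adjusted over the list alone), as in Dusp4 (64.9 ± 2.07 to 126 ± 0.939 CPM). The list had adjusted p = 0.00695, and adjusted p = 0.0577 with an estimated correlation. Neuroectoderm genes fell in 5 of 22 with Fabp7 up (6 and 3 adjusted over the list alone), as in Sox3 (19.3 ± 2.62 to 5.58 ± 1.12 CPM), and keratin and epithelial genes fell in 6 of 12 with Krt8 up (7 and 1 adjusted over the list alone), as in Epcam (270 ± 4.13 to 143 ± 4.16 CPM). Their adjusted p-values were 0.0197 and 0.00736, with 0.265 and 0.308 as adjusted p with an estimated correlation. Of 7 trophoblast genes 4 rose (4 with 1 down adjusted over the list alone), among them Cdx2 (0.309 ± 0.0561 to 4.58 ± 0.284 CPM), at a median of 3.4, or 0.94 with members at 0 counts set to their floor. As a list they had adjusted p = 0.00532, and adjusted p = 0.213 with an estimated correlation. Of 22 stress response genes 6 rose and Trib3 fell (7 and 1 adjusted over the list alone), of 25 hypoxia and glycolysis genes 2 rose and 5 fell (3 and 7), and of 89 ribosomal protein genes 22 rose and none fell (28 and none). The adjusted p-values were 0.00332, 0.032 and 1.52e-07, and adjusted p = 0.217, 0.623 and 0.578 with an estimated correlation; the hypoxia call ended without shBeclin1 replicate 2 (0.0834). Examples are Vldlr (22 ± 2.1 to 44.2 ± 0.858 CPM), Slc2a1 (571 ± 11.4 to 282 ± 3.27 CPM) and Rpl19 (1420 ± 7.3 to 1850 ± 16.4 CPM). Core autophagy genes were not called as a list (3 up, 5 down of 42, adjusted p = 0.702).

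At day 10 the question is whether cells labelled CM differ in cardiac gene expression after knockdown. The troponin gene Tnnt2 stood at 790 ± 46.5 CPM in shBeclin1 and 1.27 ± 0.748 CPM in shNT libraries, 657-fold higher (adjusted p = 9.36e-08); its log2 fold of 9.36 was 8.74 without shNT replicate 1 and 10.03 without shNT replicate 2. The atrial myosin light chain gene Myl7 stood at 603 ± 29.8 against 1.09 ± 0.187 CPM, 538-fold higher. The cardiac transcription factor genes Gata4 (111 ± 1.75 against 1.79 ± 0.319 CPM), Gata6 (132 ± 7.87 against 9.16 ± 1.32 CPM) and Myocd (59.1 ± 6.24 against 1.59 ± 0.137 CPM) were 60.7-fold, 14.6-fold and 37.4-fold higher. T, which had risen at day 4, was 594-fold lower, at 0.43 ± 0.029 against 259 ± 1.41 CPM (adjusted p = 3.3e-34). The morphogen gene Shh fell 97.7-fold from 171 ± 7.28 to 1.74 ± 0.273 CPM, and the endoderm factor gene Foxa1 fell 90.5-fold from 56.1 ± 2.49 to 0.612 ± 0.0455 CPM. In all, 3683 genes rose and 3663 fell, 1200 and 1674 of them at least 2-fold; with total counts as the scaling 36.7% rose in place of 50.1%. Shh lies on chromosome 5 at 28456815 to 28467256, where 9530036O11Rik on the opposite strand overlaps 15.7% of its exon length. Tnnt2 lies on chromosome 1 at 135836354 to 135852260 and Myl7 on chromosome 11 at 5896637 to 5898782.

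Cardiac lists rose and neural, endodermal and pluripotency lists fell at day 10, each also with an estimated correlation. Of 32 cardiomyocyte genes 31 rose and none fell, at a median of 6.93, or 6.72 with members at 0 counts set to their floor (adjusted p = 6e-35, and 0.00951 with an estimated correlation). Of 20 cardiac progenitor genes 18 rose and 2, Tbx1 and Hopx, fell, with Hand2 going from 0.566 ± 0.376 to 197 ± 2.98 CPM (log2 fold 8.33, and 9.30 without shNT replicate 1). Together the members had adjusted p = 1.21e-12, and 0.00349 with an estimated correlation. Of 20 BMP target genes 16 rose and 3, Id4, Hey1 and Grem1, fell, with Bambi rising 9.59-fold to 154 ± 6.42 CPM and Smad6 9.54-fold to 59.3 ± 1.31 CPM. The list test gave adjusted p = 1.59e-08, and 0.00349 with an estimated correlation. Of 22 Wnt target genes 7 rose and 8 fell (8 and 9 adjusted over the list alone), and the list was not called (adjusted p = 0.424), with Dkk1 rising 15.3-fold to 40.6 ± 2.64 CPM beside the fall in T. Of 36 Hox genes 24 rose and none fell, as in Hoxd8 (3.14 ± 0.0198 to 39.4 ± 1.57 CPM). Tested as a group they had adjusted p = 4.99e-08, and 0.00349 with an estimated correlation. Of 22 neuroectoderm genes 19 fell and none rose, as in Map2 (27.2 ± 1.28 to 4.26 ± 0.0166 CPM). Camera gave adjusted p = 1.94e-12, and 0.00918 with an estimated correlation. Of 14 definitive endoderm genes 11 fell and 1, Pyy, rose (adjusted p = 3.13e-08, and 0.00951 with an estimated correlation). Of 20 pluripotency genes 15 fell and 3 rose, with Sox2 going from 53.5 ± 6.56 to 8.96 ± 0.48 CPM and Tdgf1 from 24.2 ± 0.117 to 102 ± 4.15 CPM. The list had adjusted p = 2.65e-07, and 0.0293 with an estimated correlation. Of 11 formative and primed genes 9 fell and 2 rose (adjusted p = 8.86e-05, and 0.018 with an estimated correlation). Counts adjusted over the list alone equalled those over all genes for the lists of this paragraph that give 1 pair of counts.

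Muscle and immune genes also differed at day 10. Of 23 smooth muscle and fibroblast genes 13 rose and 6 fell, as in Cnn1 (4.37 ± 1.29 to 47.3 ± 0.323 CPM) and Col1a1 (369 ± 22.4 to 986 ± 89.5 CPM). As a list they had adjusted p = 0.00556, and 0.0369 with an estimated correlation. Of 21 interferon response genes 11 fell and 1, Ifit2, rose, as in Rsad2 (22.3 ± 0.623 to 3.25 ± 0.869 CPM) and Usp18 (10.3 ± 1.02 to 0.705 ± 0.00413 CPM). Together the members had adjusted p = 8.94e-05, and 0.00951 with an estimated correlation. Of 16 Nodal and Activin pathway genes 9 rose and 5 fell, with Smad7 rising from 10 ± 0.141 to 52.2 ± 1.39 CPM (adjusted p = 0.00527, and 0.0369 with an estimated correlation). Of 42 core autophagy genes 15 rose and only Becn1 fell, as in the autophagy receptor genes Sqstm1 (174 ± 5.93 to 314 ± 3.18 CPM) and Calcoco1 (82.2 ± 2.42 to 131 ± 3.68 CPM), at a median of 0.15. The list test gave adjusted p = 0.00293, and 0.0432 with an estimated correlation. Streak genes were not called as a list (3 up, 3 down of 16, adjusted p = 0.808); Evx1 was at least 49.6-fold higher and Cer1 at least 12.4-fold lower beside T. Called only with the preset correlation were BMP ligands and receptors (11 up, 5 down of 21), BMP antagonists (2 up, 7 down of 13, and 2 and 8 adjusted over the list alone), Notch genes (2 up, 9 down of 15, and 3 and 9) and blood and endothelial genes (10 up, 4 down of 23). In this order the adjusted p-values were 0.0222, 0.000679, 0.029 and 0.016, and adjusted p = 0.383, 0.132, 0.132 and 0.132 with an estimated correlation; the Notch call also ended under total counts (0.0619) and the strict low-count filter (0.0616). Examples are Bmp4 (19.4 ± 0.317 to 117 ± 3.48 CPM), Fst (39.4 ± 1.82 to 2.8 ± 0.592 CPM) and Hey2 (4.5 ± 0.353 to 37.1 ± 2.88 CPM). The same held for keratin and epithelial genes (1 up, 9 down of 12, and 1 and 10 adjusted over the list alone), hypoxia and glycolysis genes (16 up, 2 down of 25, and 18 and 2), oxidative metabolism genes (23 up, 2 down of 30, and 25 and 2) and ribosomal protein genes (1 up, 14 down of 89, and none and 10). Adjusted p-values of these lists were 2.27e-06, 1.24e-05, 4.99e-08 and 0.00799, and adjusted p = 0.0661, 0.367, 0.2 and 0.754 with an estimated correlation; the ribosomal call ended without shNT replicate 2 (0.0732) and shBeclin1 replicate 1 (0.835). Cdh1 fell from 139 ± 3.83 to 23.2 ± 5.11 CPM, Hk2 rose from 147 ± 5.55 to 278 ± 20.8 CPM and the fatty acid transporter gene Cd36 fell from 199 ± 10.8 to 4.8 ± 0.497 CPM. Lists given here with 1 pair of counts kept it when adjusted over the list alone.

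At day 10 without GF the same question is asked in the other culture. Tnnt2 stood at 761 ± 306 CPM in shBeclin1 and 1.22 ± 0.027 CPM in shNT libraries, 620-fold higher (adjusted p = 6.39e-08), and Gata4 at 158 ± 19.8 against 0.179 ± 0.0101 CPM, 850-fold higher (adjusted p = 3.01e-32). The epicardial genes Wt1 (94.7 ± 8.65 against 0.327 ± 0.0236 CPM) and Bnc1 (120 ± 14.6 against 0.298 ± 0.0169 CPM) were 283-fold and 394-fold higher. The myosin binding protein gene Mybpc3 stood at 135 ± 66.5 CPM against 2 counts in the shNT group, a ratio of 2320 with a counting interval of 642 to 19200. Its log2 fold of 10.98 was 14.15 without shNT replicate 1, 10.01 without shNT replicate 2 and 10.36 without shBeclin1 replicate 2. Neuronal genes fell, with Map2 going from 215 ± 7.6 to 5.78 ± 0.45 CPM (37.2-fold, adjusted p = 3.85e-32) and Elavl4 from 182 ± 5.52 to 3.13 ± 0.491 CPM (58.3-fold). Otx2, a factor of forebrain and primed cells, fell 165-fold from 235 ± 3.62 to 1.37 ± 1.06 CPM, a log2 fold of -7.36 that was -8.53 without shBeclin1 replicate 2. T was 28.8 ± 0.741 CPM in shNT and 0.152 ± 0.214 CPM in shBeclin1 libraries, a log2 fold of -7.42 that was -6.53 without shBeclin1 replicate 1 and -11.89 without shBeclin1 replicate 2. In all, 5235 genes rose and 5231 fell, 2129 and 2004 of them at least 2-fold. Wt1 lies on chromosome 2 at 105126529 to 105173616, Mybpc3 on chromosome 2 at 91118144 to 91136516 and Map2 on chromosome 1 at 66175273 to 66442583.

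At day 10 without GF 9 lists were called with both correlations, with heart, epicardium, vessel, muscle, BMP target and Hox genes up and neural and pluripotency genes down. Of 32 cardiomyocyte genes 31 rose and 1, Casq2, fell, at a median of 6.56, or 6.44 with members at 0 counts set to their floor (adjusted p = 4.65e-23, and 0.023 with an estimated correlation). Of 20 cardiac progenitor genes 18 rose and 1, Tbx1, fell, as in Gata6 (0.838 ± 0.132 to 205 ± 8.51 CPM). Tested as a group they had adjusted p = 6.61e-13, and 0.00959 with an estimated correlation. Of 10 epicardial genes 9 rose and 1, Sema3d, fell, as in Upk1b (0.773 ± 0.0405 to 72.3 ± 3.72 CPM). Camera gave adjusted p = 6.09e-06, and 0.0169 with an estimated correlation. In the CM culture the epicardial list had 5 up and 3 down and was not called (adjusted p = 0.222). Of 23 blood and endothelial genes 19 rose and 1, Runx1, fell (21 and 1 adjusted over the list alone), as in Kdr (7.56 ± 0.331 to 78.6 ± 7.9 CPM). The list had adjusted p = 8.04e-08, and 0.0135 with an estimated correlation. Of 23 smooth muscle and fibroblast genes 16 rose and 4 fell, as in Col1a1 (276 ± 2.46 to 1600 ± 2.19 CPM) and Postn. As a list they had adjusted p = 6.23e-05, and 0.0135 with an estimated correlation. Of 20 BMP target genes 15 rose and 4, Msx1, Id3, Tfap2a and Id4, fell (adjusted p = 0.000147, and 0.0169 with an estimated correlation), with Bambi rising 10.5-fold to 143 ± 11.6 CPM. Of 36 Hox genes 16 rose and none fell, as in Hoxb4 (0.119 ± 0.00675 to 23.6 ± 1.47 CPM), at a median of 2.20, or 2.00 with members at 0 counts set to their floor. Together the members had adjusted p = 0.000897, and 0.0214 with an estimated correlation. Of 22 neuroectoderm genes 20 fell and 1, Pax6, rose, at a median of -6.20, or -6.06 with members at 0 counts set to their floor. The list test gave adjusted p = 2.8e-14, and 0.0117 with an estimated correlation. Of 20 pluripotency genes 17 fell and 2, Klf4 and Tdgf1, rose, as in Sox2 (144 ± 7.7 to 5.11 ± 0.432 CPM). Tested as a group they had adjusted p = 1.06e-09, and 0.0169 with an estimated correlation. For the lists above that give 1 pair of counts, the counts adjusted over the list alone were equal to it.

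Further lists at day 10 without GF were called with the preset correlation only. Of 22 Wnt target genes 14 fell and 2, Bambi and Cdx2, rose, as in Apcdd1 (103 ± 17.4 to 3.88 ± 0.165 CPM), and of 16 streak genes 8 fell and 1, Evx1, rose, as in Sp5 (5.84 ± 0.246 to 1.12 ± 0.435 CPM). Their adjusted p-values were 0.000163 and 0.0122, and for both lists adjusted p = 0.062 with an estimated correlation. Of 89 ribosomal protein genes 84 fell and 2, Rps4l and Rpl39l, rose (85 and 2 adjusted over the list alone), as in Rpl5 (2350 ± 30 to 1510 ± 33.1 CPM), and of 25 cell cycle genes 21 fell and none rose, as in Pcna (205 ± 5.25 to 100 ± 20.5 CPM). The adjusted p-values were 1.1e-17 and 3.82e-07, and adjusted p = 0.28 and 0.265 with an estimated correlation; the ribosomal median was -0.50, and -0.52 under total counts. Of 42 core autophagy genes 20 rose and 4, Becn1, Atg12, Pik3c3 and Atg5, fell, as in Sqstm1 (99.8 ± 1.81 to 195 ± 8.54 CPM), and of 37 lysosome genes 20 rose and 3, Gla, Npc2 and Scarb2, fell, as in Ctsb (157 ± 1.45 to 264 ± 6.92 CPM). In this order the adjusted p-values were 0.0283 and 0.000708, and adjusted p = 0.135 and 0.186 with an estimated correlation. Of 30 oxidative metabolism genes 26 rose and none fell, as in Cpt1a (16.6 ± 1.93 to 52.8 ± 7.12 CPM), of 12 keratin and epithelial genes 8 rose and 2 fell, as in Krt8 (46.5 ± 2.54 to 314 ± 40.7 CPM), and of 16 immediate early genes 10 rose and 1, Btg2, fell, as in Jun (33.8 ± 0.238 to 58.4 ± 0.578 CPM). Adjusted p-values of these lists were 1.62e-06, 0.00189 and 0.00627, and adjusted p = 0.254, 0.211 and 0.186 with an estimated correlation. Of 20 p53 target genes 5 rose and 12 fell, as in Plk2 (53.5 ± 0.68 to 141 ± 11.4 CPM) and Aen (83.9 ± 1.37 to 38.9 ± 0.485 CPM). BMP ligands and receptors (14 up, 4 down of 21), Notch genes (4 up, 9 down of 15) and formative genes (3 up, 7 down of 11, and 3 and 8 adjusted over the list alone) included Smad9 (4.98 ± 0.982 to 37.8 ± 0.805 CPM), Notch1 (48.8 ± 3.64 to 14 ± 0.259 CPM) and Dnmt3a (141 ± 0.835 to 295 ± 10 CPM). The adjusted p-values of these 4 lists were 0.0132, 0.00795, 0.0161 and 0.0178, and adjusted p = 0.265, 0.265, 0.118 and 0.118 with an estimated correlation; the Notch call ended under the strict low-count filter (0.0514). Interferon response genes were not called here (5 up, 3 down of 21, and 4 and 2 adjusted over the list alone, adjusted p = 0.579). Lists with 1 pair of counts here also kept it when adjusted over the list alone.

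**Figure D3:**
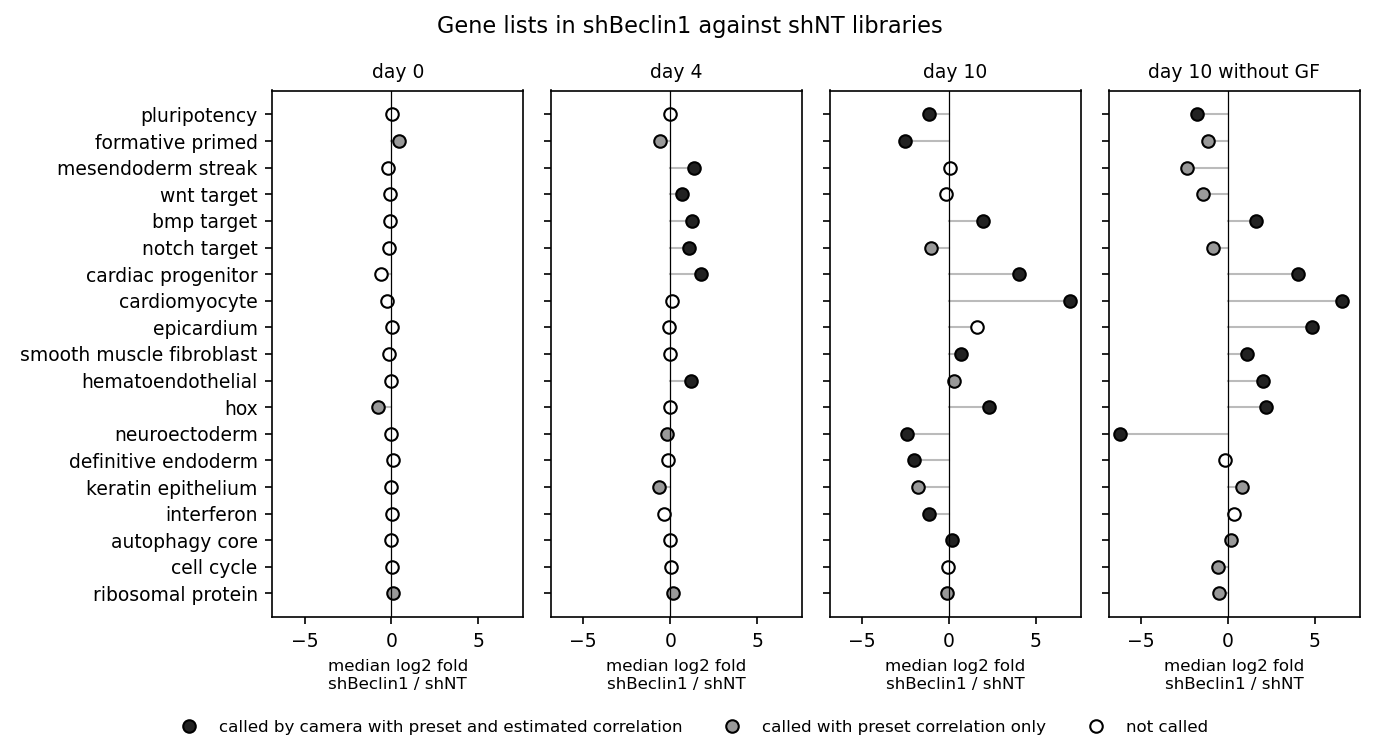
Median log2 fold change of shBeclin1 over shNT libraries (horizontal axis) for 19 of the 37 gene lists (vertical axis) at day 0, day 4, day 10 and day 10 without GF; black points were called by camera with preset and estimated correlation, grey points with the preset one only, and white points were not called. The cardiomyocyte list lies at 6.93 at day 10 and 6.56 without GF, and the neuroectoderm list at -2.43 and -6.20.

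**Figure D4:**
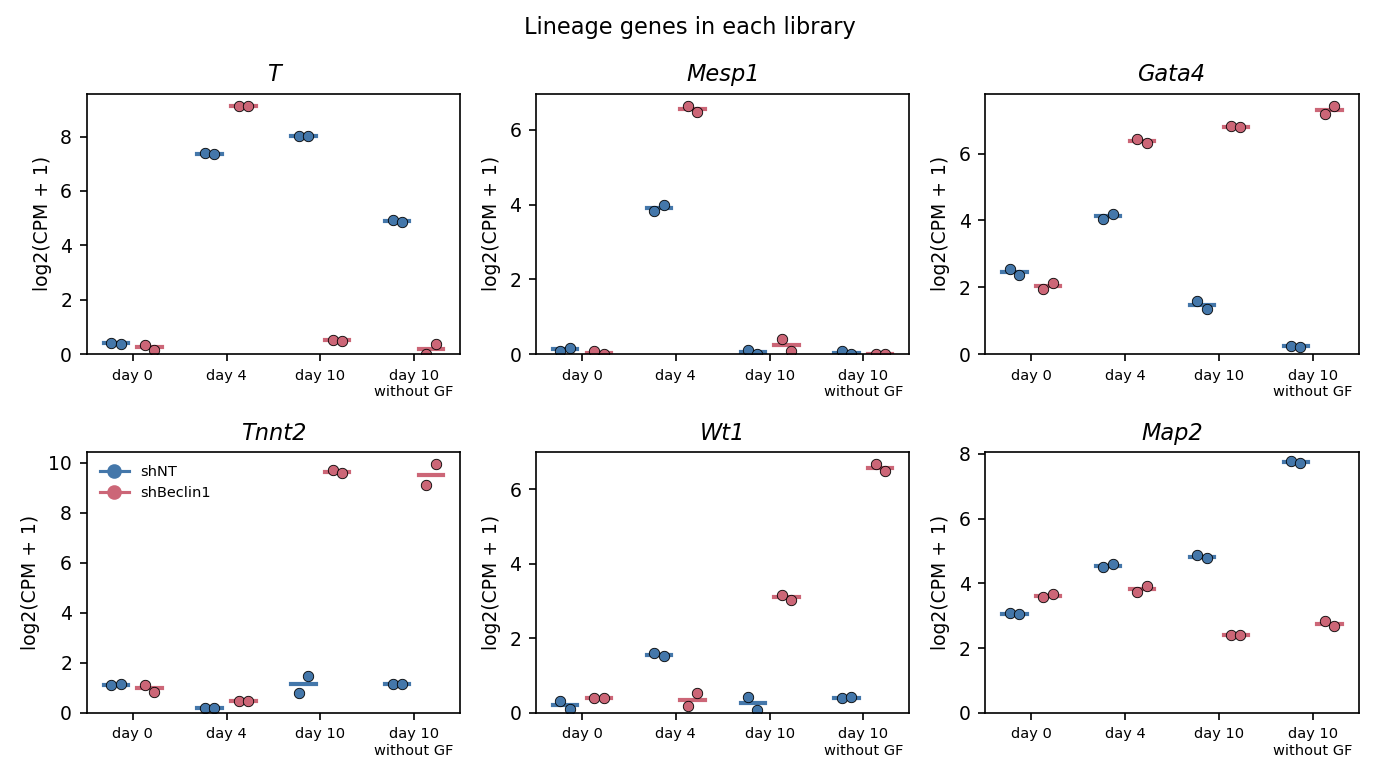
Log2(CPM + 1) of 6 lineage genes (vertical axes) by day, with points for libraries, lines for the mean of 2 and colour for the hairpin. T is higher in shBeclin1 libraries at day 4 and lower at both day 10 conditions, while the mean of Tnnt2 in shBeclin1 libraries is 790 CPM at day 10 and 761 CPM without GF.

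The 2 day 10 cultures were also compared within each hairpin. In shNT libraries the endothelial scavenger receptor gene Stab1 was 207-fold higher in the CM cultures (180 ± 3.55 CPM) than in those without GF (0.861 ± 0.0777 CPM), Arg1 was 51.7-fold higher (62.1 ± 3.86 against 1.2 ± 0.152 CPM) and Tie1 was 38.8-fold higher (92.6 ± 0.603 against 2.39 ± 0.304 CPM). Wnt1 was 163-fold lower (0.282 ± 0.0267 against 46.6 ± 6.97 CPM). In all, 5152 genes were higher and 4951 lower, 3383 of them at least 2-fold. In shBeclin1 libraries Hoxd8 was 40.7-fold higher in the CM cultures (39.4 ± 1.57 against 0.948 ± 0.374 CPM) and Etv4 15.2-fold higher (28.1 ± 3.57 against 1.86 ± 0.195 CPM), while the epicardial gene Tbx18 was 52-fold lower (2.16 ± 0.418 against 114 ± 1.15 CPM) and Grhl3 38.7-fold lower (1.42 ± 0.182 against 54.9 ± 6.08 CPM). Of the genes called there, 3883 were higher and 3195 lower, 2070 of them at least 2-fold; with total counts as the scaling 42.2% were higher, against 54.9% with TMM.

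A further comparison asks whether shBeclin1 cells without GF matched shNT cells of the CM culture. Tnnt2 stood at 761 ± 306 against 1.27 ± 0.748 CPM, 633-fold higher, with a log2 fold of 9.31 that was 8.71 without the day 10 shNT replicate 1 and 9.98 without replicate 2. Hand2os1, a noncoding gene beside Hand2, stood at 249 ± 6.29 against 0.134 ± 0.0655 CPM and the mesothelial gene Upk3b at 129 ± 29.4 against 0.186 ± 0.0771 CPM. Car3 fell 115-fold from 216 ± 10.2 to 1.87 ± 0.145 CPM and Lepr 73.5-fold from 115 ± 12.2 to 1.56 ± 0.208 CPM. In all, 4210 genes were higher and 4948 lower, 3437 of them at least 2-fold.

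Whether the effect of the hairpin differed between days was tested directly as a difference of log2 folds. From day 0 to day 4 the growth factor gene Fgf10 turned from down (-0.91) to up (2.25), a difference of 3.17 (SE 0.18, adjusted p = 1.66e-15). For Phlda2, not called at day 0, the difference was 3.02 (SE 0.18, adjusted p = 4.65e-15), and Foxd3 turned from up (0.53) to down (-1.88), a difference of -2.41 (SE 0.23, adjusted p = 8.5e-10). By day 10 the effect had grown for Tnnt2 by 9.63 (SE 1.64, adjusted p = 0.00226), which was 8.99 without the day 10 shNT replicate 1 and 10.30 without replicate 2, and for Myl7 by 9.49 (SE 0.85, adjusted p = 3.05e-05). For the netrin gene Ntn1 it was lower, at -5.34 (SE 0.34, adjusted p = 2.63e-14), as for Adgrv1, which turned from up (0.5) to down (-5.99), at -6.50 (SE 0.22, adjusted p = 3.2e-22). Between the day 10 cultures, the effect in the CM culture exceeded that without GF for Dkk1 by 6.82 (SE 0.19, adjusted p = 2.27e-25) and for Tubb3 by 5.18 (SE 0.33), and was below it for Smoc2, at -6.75 (SE 0.21), and Cd36, at -5.91 (SE 0.18). The numbers of genes called were 2836 (1517 up, 1319 down), 5283 (2786 up, 2497 down) and 6584 (3104 up, 3480 down). Lists called in these tests with an estimated correlation numbered 8, 11 and 7, of 16, 21 and 20 with the preset one. In the difference of day 4 and day 0, the streak (1.70), cardiac progenitor (2.39), BMP target (1.31), Wnt target (0.99) and blood and endothelial (1.77) medians rose, with adjusted p = 0.0201, 0.0119, 0.0149, 0.0474 and 0.026 with an estimated correlation. For day 10 and day 0, the cardiomyocyte (7.11) and cardiac progenitor (4.63) medians rose and the neuroectoderm median (-2.53) fell, with adjusted p = 0.01, 0.00316 and 0.01 with an estimated correlation. Between the day 10 cultures the epicardial (-3.02), blood and endothelial (-1.35) and interferon (-0.92) medians were lower in the CM culture and the neuroectoderm (3.13) and Wnt target (1.34) medians higher, with adjusted p = 0.0286, 0.0376, 0.0304, 0.0326 and 0.0376 with an estimated correlation. The sign of median and mean differed for 3 called lists: neuroectoderm from day 0 to day 4 (median -0.13, mean 0.07, tested down), smooth muscle from day 0 to day 10 (0.16, -0.06, tested up) and oxidative stress genes from day 0 to day 10 (-0.36, 0.25, tested down). In this order they had adjusted p = 0.325, 0.0272 and 0.119 with an estimated correlation.

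Genes that follow normal differentiation were taken from shNT libraries outside each comparison, 200 raised and 200 lowered, to ask whether knockdown moved them along. The lists for day 4 and for day 10 without GF came from day 10 against day 0. Those for day 0 came from day 10 against day 4, and those for day 10 from day 10 without GF against day 0. In shNT libraries Tnnt2 stood at 1.27 CPM and Myl7 at 1.09 CPM at day 10, and at 1.22 and 1.33 CPM without GF. The lists thus follow what shNT cultures became and say little of cardiomyocyte formation. At day 4, 70 of the genes raised by day 10 rose and 31 fell (median 0.39, adjusted p = 1.59e-05, and 0.00143 with an estimated correlation), and of the lowered ones 19 rose and 49 fell (median -0.19, adjusted p = 0.000489, and adjusted p = 0.0511 with an estimated correlation). At day 0, 8 of the raised genes rose and 32 fell (median -0.22, adjusted p = 0.0328), and the lowered ones were not called (39 up, 17 down, adjusted p = 0.106). At day 10 the raised genes went both ways (73 up, 89 down, adjusted p = 0.315) while 113 of the lowered ones fell further and 29 rose (median -0.80, adjusted p = 4.22e-09, and 0.0146 with an estimated correlation). At day 10 without GF, 115 raised genes rose and 64 fell (median 0.54, adjusted p = 0.00126), and 118 lowered ones fell and 24 rose (median -0.88, adjusted p = 5.8e-10, and 0.00497 with an estimated correlation for both lists). The call of raised genes at day 0 ended without shNT replicate 1 (median -0.06), shNT replicate 2 (-0.11) or shBeclin1 replicate 1 (median 0), at adjusted p up to 0.235.

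The 4 knockdown comparisons share no libraries, so their overlap shows which genes changed at every point. In all 4 comparisons 37 genes rose, against 6.2 if calls were independent, and 59 fell, against 7.6. With total counts as the scaling fewer genes rose and more fell in all 4, and few passed a fold of at least 2, as given below. Besides Becn1, genes down in all 4 included the BMP antagonist Chrd (log2 folds -1.18, -1.15, -3.44 and -1.35) and Thy1 (-0.94, -0.84, -2.70 and -2.58), and genes up in all 4 included H19 (1.5, 1.27, 0.71 and 2.05) and Cdh2 (0.76, 1.18, 1.12 and 0.64), all chosen after their values were seen. By number of genes the largest pairwise overlap was between the day 10 cultures, where 2400 genes rose in both against 1007 expected and 2027 fell in both against 1001, while 357 and 539 went opposite ways. Relative to expectation, shared falls were more frequent between day 4 and day 10 (814 against 369). Between day 0 and day 10 without GF the overlap was 288 rises against 303 expected (Fisher's exact test, two-sided p = 0.298) and 380 falls against 395 (p = 0.357). Genes called at day 0 also went the opposite way more often than expected at each later point, counts whose expectation was computed after they were seen. Of the day 0 rises 177 fell at day 4 against 112 expected, 249 at day 10 against 212 and 423 without GF against 303. Of the day 0 falls 215 rose at day 4 against 155 expected, 419 at day 10 against 278 and 615 without GF against 395. At day 4 and day 10 the calls shared with day 0 in the same direction exceeded expectation too (161 rises against 119 and 280 falls against 146 at day 4, 261 against 213 and 395 against 277 at day 10). Across genes, which are not independent replicates, log2 folds of the day 10 cultures correlated at Pearson 0.58 and Spearman 0.45, and other pairs at Pearson -0.02 to 0.11.

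Of the lists, 7 were called in none of the 4 knockdown comparisons. Wnt ligands and receptors had 12 up and 7 down of 37 at day 4, with adjusted p-values of 0.592, 0.171, 0.972 and 0.579 in time order. Wnt antagonists had 6 up and 5 down of 16 at day 10 (0.666, 0.226, 0.894 and 0.497), visceral endoderm and liver genes 8 up and 5 down of 14 without GF (0.801, 0.63, 0.643 and 0.113) and skeletal muscle genes 3 up and 4 down of 7 without GF (0.666, 0.815, 0.728 and 0.93). Oxidative stress genes of the Nrf2 pathway had 3 up and 9 down of 14 without GF (0.571, 0.403, 0.117 and 0.437), mitochondrially encoded genes 5 up and none down of 13 at day 10 (0.451, 0.815, 0.0508 and 0.679; called without shBeclin1 replicate 1, 0.0218) and replication histone genes none up and 1 down of 9 without GF (0.592, 0.403, 0.728 and 0.97). Sfrp5, a Wnt antagonist, rose by 7.17 in log2 without GF, Afp rose by 3.33 at day 10 and Pax7 fell by 4.62 at day 10, each chosen after its value was seen.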

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

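Of the tests in this part, the comparison of day 10 with day 4, Becn1 in the differences between points and the tests on explanations were chosen only after results were seen. The results below stood out because the effect of the hairpin differed between 2 points, by a test of that difference in edgeR or camera. Genes whose effect differed numbered 2836 from day 0 to day 4, 5283 from day 0 to day 10, 6584 between the day 10 cultures and 4993 from day 4 to day 10 (2338 up, 2655 down).

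From day 0 to day 4 the formative and primed list turned from up to down (median difference of log2 folds -0.92, adjusted p = 9.51e-05, and 0.026 with an estimated correlation). Over the same interval the stress response list turned from down to up (0.23, adjusted p = 4.98e-05, and adjusted p = 0.0983 with an estimated correlation). Cacna1c, a calcium channel gene of heart muscle, turned from down to up, with a difference of 3.24 (adjusted p = 4.42e-06), as did the caudal factor gene Cdx1 with 3.55 (adjusted p = 5.25e-05).

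From day 0 to day 10 the formative list also turned from up to down (-2.17, and 0.013 with an estimated correlation), and the Hox list turned from down to up (3.13, and 0.00316 with an estimated correlation). The day 0 calls of the lists named so far were lost with an estimated correlation (adjusted p = 0.405 for the formative and Hox lists, 0.74 for the stress response list). The Hox call at day 0 also ended with total counts (0.156), with the strict low-count filter (0.175), in 3 of 4 leave-one-out fits (0.0575, 0.0848 and 0.0837) and had no member called over the list alone. The formative call ended in 2 of 4 (0.13 and 0.085), as did that of the stress response list (0.151 and 0.0546), and at day 4 both lists were called with the preset correlation only (0.0571 and 0.217). Hypoxia and glycolysis genes turned up (0.59) and ribosomal protein genes turned down (-0.21), with adjusted p = 0.211 and 0.634 with an estimated correlation. At day 0 and at day 10 by themselves both of these lists were called with the preset correlation only. Single genes that turned from down to up were Ace (4.81), Cacna1c (3.97), Cacna1h (2.99), Hoxa10 (7.96) and the BMP effector gene Smad9 (4.01), and from up to down Dppa3 (-3.72) and Fgfr2 (-3.05). At day 0 the calls of some of these ended in leave-one-out fits: Cacna1c without shNT replicate 2 (adjusted p = 0.0642) or shBeclin1 replicate 1 (0.0847), Cdx1 without shNT replicate 2 (0.146), shBeclin1 replicate 1 (0.123) or replicate 2 (0.115), and Smad9 without shNT replicate 1 (0.131) or shBeclin1 replicate 1 (0.102). Hoxa10 at day 0 rested on few counts, with a ratio of 11.8 (counting interval 1.74 to 503), and its call ended without shNT replicate 1 (0.0702), shNT replicate 2 (0.13), shBeclin1 replicate 1 (0.277) or shBeclin1 replicate 2 (0.104).

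Between the day 10 cultures keratin and epithelial genes were lower after knockdown in the CM culture and higher without GF (-2.74, and 0.0354 with an estimated correlation), while each direction by itself was called with the preset correlation only (adjusted p = 0.0661 and 0.211 with an estimated one). The Wnt antagonist gene Dkk1 (6.82), the Wnt effector gene Lef1 (3.07), Lmo1 (3.81) and Tbx3 (2.83) rose after knockdown in the CM culture and fell without GF. The blood and vessel factor gene Etv2 (-3.56) and Mal2 (-6.38) did the reverse.

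From day 4 to day 10 the Notch list turned from up to down (-1.99, and 0.0369 with an estimated correlation), with its ligand genes Dll1 (-4.55) and Dll3 (-4.50). For the Notch fall at day 10 alone, adjusted p = 0.132 with an estimated correlation. The hypoxia list turned up (0.58) and the ribosomal protein list down (-0.24), with adjusted p = 0.278 and 0.512 with an estimated correlation. At day 4 and at day 10 by themselves the hypoxia and ribosomal protein lists were called with the preset correlation only. Apcdd1 (-2.58), Car3 (-9.40), Cd36 (-8.14), Etv2 (-4.09), Six2 (-8.84), T (-10.97) and Usp18 (-6.59) turned from up to down, and Wt1 (7.67) from down to up. The Becn1 difference was also smaller at day 10 than at day 4, by 0.32 (adjusted p = 0.0277), but it was not called with total counts (0.28, adjusted p = 0.052) or in 7 of 8 leave-one-out fits. These were the fits without day 4 shNT replicate 1 (0.0828), day 4 shNT replicate 2 (0.0677), day 4 shBeclin1 replicate 1 (0.2), day 10 shNT replicate 1 (0.0753), day 10 shNT replicate 2 (0.0823), day 10 shBeclin1 replicate 1 (0.0794) and day 10 shBeclin1 replicate 2 (0.0646).

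The smaller Becn1 difference at day 10 than at day 0 (0.51, SE 0.11) was weighed against scaling and against a return of Becn1. Scaling between libraries is argued against, since the smaller of the values with size factors and with total counts was 0.47. From day 0 to day 10 the log2 change of Becn1 was -0.06 in shBeclin1 libraries (SE 0.08, upper 95% limit 0.1) and -0.56 in shNT libraries (adjusted p = 8.79e-09). A partial return of Becn1 in shBeclin1 cells may offset such a fall, and a remainder of Becn1 RNA that does not follow the fall may give the same values. Both stay open, because bulk libraries do not separate cells that kept the hairpin from cells that lost it.

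T, higher after knockdown at day 4 and lower at day 10, was weighed against 4 explanations. Exchanged hairpin labels at a point are argued against, since the lowest shNT library held at least 1.35 times the Becn1 of the highest shBeclin1 library at each point. Streak-like cells left in day 10 shNT cultures are argued against, since the other 15 streak genes changed there by a median of -6.16 from day 4 to day 10 (75th percentile -4.06, 14 down) while T changed by 0.65 (SE 0.07). This test replaced a first one, the median of these genes after knockdown at day 10, which was 0.11 with 3 up and 2 down (adjusted p = 0.79) and decided nothing. Notochord-like cells in day 10 shNT cultures may be a source, and stay open: 10 notochord genes other than T, Shh, Foxa1, Foxa2, Chrd and Car3 had a median of -0.14 after knockdown with 4 up and 5 down (adjusted p = 0.575). Values of Foxj1 and Nog among them had been seen when the list was written, and the 8 others had the same median with 3 up and 4 down. Since members went both ways and some are also used by other tissues, the bound written for this test, a list not called down, was wrong to count as an exclusion. The left-out genes T, Car3, Shh, Foxa1, Foxa2 and Chrd all fell at day 10, with log2 folds of -9.21, -7.87, -6.61, -6.5, -6.02 and -3.44. They are no separate test, since T is the pattern itself and Car3, Shh and Foxa1 were named as largest falls. Separate cultures or batches of the hairpins stay open too, since 0 batches in the labels hold libraries of both hairpins.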

How the results depend on the processing

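The comparison of day 10 with day 4 and Becn1 in the differences between points were the only results here chosen after results were seen; the other tests and settings were planned. Of 2690 values of named genes under the alternatives, 2637 stayed on their side of the threshold and 53 lost their call. None reversed with a call in the main or the alternative fit. Of the losses, 41 were at day 0, over 14 of 45 named genes, 2 at day 4 (Atg5 without shNT replicate 2, adjusted p = 0.145, and without shBeclin1 replicate 2, 0.0988), none at day 10 in either culture, 2 in the difference of day 4 and day 0 (Cyp26a1 without day 0 shNT replicate 1, 2.45, adjusted p = 0.184; Enpp2 without day 0 shBeclin1 replicate 2, -2.20, adjusted p = 0.0548) and 8 for Becn1 between day 10 and day 4. DESeq2 gave no adjusted p for 2 further values (Cdx1 and Hoxa10 at day 0). Of 3027 list values 2806 stayed, 130 lost a call, 87 gained one and 4 reversed. For genes and lists, a change of sign where neither fit made a call was counted as staying. With a replicate block Id2 (0.56, adjusted p = 0.118) and Hoxa10 (-3.29, adjusted p = 0.0558) lost their call at day 0, and the counts were 2690 at day 0, 4065 at day 4, 7325 at day 10 and 10407 without GF.

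A fold of at least 2, which by construction keeps fewer genes, left 294 at day 0, 963 at day 4, 2874 at day 10 and 4133 without GF. It left 6610 for day 4 and 7835 for day 10 against day 0 in shNT, 3383 and 2070 between the cultures in shNT and shBeclin1, 3437 for shBeclin1 without GF against shNT, and 897, 2240 and 2523 for the 3 planned differences between points. Of genes called in all 4 comparisons it left 1 up and 2 down, and total counts gave 16 up and 104 down; for the latter the cause was not tested. Fitting only the groups compared gave 1241 genes at day 0, where the cause was not tested, 5693 at day 4, 7877 at day 10 and 9833 without GF. Leave-one-out fits, where the lone library of a group is assumed to vary like the others, gave 920 to 3011 genes at day 0 and 2514 to 2644 at day 4, with fewer libraries; the other counts stayed within 1.5 times, at 5726 to 6186 for day 10 and 8778 to 9907 without GF.

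The estimated correlation left no list called at day 0 (0 lists), 6 at day 4, 12 at day 10 and 9 without GF, and 8, 11 and 7 for the differences, and it ended the call of lowered differentiation genes at day 4 (-0.19, adjusted p = 0.0511). It allows for members that vary together as far as they do in these data, while the preset value of 0.01 allows for a small fixed amount. At day 4 fry called 26 lists. Lists called at day 0 ranged from 2 to 5 in leave-one-out fits. The ribosomal protein list reversed at day 0 without shNT replicate 2 (-0.01, adjusted p = 0.953; range -0.01 to 0.23) and for day 4 minus day 0 without day 0 shNT replicate 1 (-0.08, adjusted p = 0.00199; range -0.08 to 0.16). Under fry, which asks another question, Wnt antagonists at day 10 (0.19, adjusted p = 0.00105) and Nrf2 genes without GF (-0.24, adjusted p = 0.000296) had the opposite direction to camera. Raised differentiation genes at day 0 were not called with 100 genes (-0.18, adjusted p = 0.353) and ranged from -0.26 to 0 in leave-one-out fits; lowered ones were called with 400 genes (0.05, adjusted p = 0.0216). The cause was not tested for these lists. No list called by camera changed direction with RLE factors or total counts. With 2 libraries per group, genes with few counts such as Hopx and Hoxa3 at day 0, and folds against near 0 counts such as those of Mybpc3, are limited by depth.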

Other observations

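Of the tests in this part, those of the added imprinted, germ cell, sinusoidal endothelium and macrophage lists and those on explanations of the replicate difference were chosen only after results were seen. Imprinted genes, which are expressed from the copy of 1 parent, were among the abundant genes that rose after knockdown at day 10. Igf2r stood at 3160 ± 124 CPM in shBeclin1 against 689 ± 30.9 CPM in shNT libraries, Dlk1 at 579 ± 2.27 against 36 ± 1.4 CPM (log2 fold 4.01, adjusted p = 5.68e-32) and Peg3 at 2510 ± 57.6 against 1090 ± 33.2 CPM, while Peg10 was lower, at 1370 ± 23.2 against 2550 ± 80.5 CPM. Without GF, Plagl1 rose from 85.3 ± 5.58 to 639 ± 37.7 CPM and H19 from 125 ± 6.71 to 516 ± 0.998 CPM, and there Peg10 rose too (log2 fold 1.15). Of 28 imprinted genes 19 rose and 4 fell at day 10 (median 0.65, adjusted p = 1.45e-06, and 0.0211 with an estimated correlation), with 20 and 3 without GF (median 0.99, adjusted p = 1.15e-05, and 0.0329 with an estimated correlation). At day 4 there were 14 up and 7 down (median 0.38, adjusted p = 0.00271), with Peg10 rising from 168 ± 3.02 to 648 ± 9.75 CPM, and at day 0 there were 7 up and 3 down (median 0.26, adjusted p = 0.00989); for both, adjusted p = 0.143 with an estimated correlation. For these lists the counts adjusted over the list alone were the same, except 10 up and 6 down at day 0. Values of 21 of these genes had been seen when the list was written, so these p-values partly restate them. The 7 others, which may vary with the 21 seen, were called up with the preset correlation only. They had 1 up and none down at day 0 and 4 and 1 at day 4. There were 5 and 1 at day 10 (adjusted p = 0.00317) and 5 and none without GF (0.0162). With an estimated correlation these had adjusted p = 0.0671, 0.0562, 0.0789 and 0.0732.

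Germ cell genes and vessel genes differed at some points, with the preset correlation only. Of 14 germ cell genes 7 fell and none rose at day 0 (none up and 8 down adjusted over the list alone; median -0.40, adjusted p = 0.00989, and adjusted p = 0.143 with an estimated correlation), as in Mael (23.9 ± 1.07 to 14.4 ± 0.351 CPM), and 4 fell at day 10 (adjusted p = 0.0359, and adjusted p = 0.164 with an estimated correlation). They were not called at day 4 (none up, 1 down, median 0.10, adjusted p = 0.743) or without GF (2 up, 7 down, median -0.71, adjusted p = 0.134). Of 8 sinusoidal and lymphatic endothelium genes 6 rose and 1 fell without GF (median 2.64, adjusted p = 0.0068, and adjusted p = 0.0605 with an estimated correlation), as in Stab2 (0.181 ± 0.0945 to 6.43 ± 0.631 CPM) and Oit3 (0 to 38.9 ± 7.77 CPM). Without Oit3, seen when the list was written, 5 rose and 1 fell (median 2.26, adjusted p = 0.0168, and adjusted p = 0.0732 with an estimated correlation). In shNT libraries 5 of the 8 genes were higher in the CM culture than without GF and 1 was lower (median 3.56, adjusted p = 0.0104, and adjusted p = 0.108 with an estimated correlation), with Stab2 at 21.9 ± 0.0147 CPM. Of 5 macrophage genes 4 rose and 1 fell at day 10, and the list was not called (median 2.97, adjusted p = 0.0942). The rises rested on few counts per group. From shNT to shBeclin1 these were 22 to 48 for Csf1r, 3 to 21 for Tyrobp, 3 to 37 for Cx3cr1 and 1 to 27 for Ptprc. The endoderm and floor plate gene Foxa2 fell at day 10 from 14.5 ± 1.22 to 0.222 ± 0.232 CPM and without GF from 47.9 ± 2.92 to 1.84 ± 0.185 CPM.

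Cardiomyocyte genes differed between the 2 day 10 shBeclin1 libraries without GF, with Tnnt2 at 544 and 977 CPM, Myh6 at 538 and 1260 CPM and Myl7 at 543 and 824 CPM. All 32 members were higher in replicate 2, against 44.8% of all genes, at a median log2 difference of 0.76. Counting depth and scaling, which move genes of like abundance alike, are argued against, since the medians of 1000 sets of other genes of like abundance lay between -0.13 and 0.09. Transcript length bias is argued against as well, since sets of like exon length gave medians from -0.13 to 0.09. These tests replaced a comparison with single genes and the removal of a trend with exon length, which did not decide. A different share of cardiomyocyte-like cells in the 2 libraries may be a source and stays open. The differences had an interquartile range of 0.30, wider than 0.28, a range that few sets of like abundance passed (median 0.19). They did not follow 1 common factor closely, but this does not argue against a different share. Members that other cells also express would follow a share less, which was not tested as a source of this range. Bulk libraries do not separate a share of cells from expression per cell. Of 25 cell cycle genes 0 were higher in replicate 2 (median -0.25) and of 25 hypoxia and glycolysis genes 24 were (median 0.30), so genes of other functions differed between the libraries too.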
